A study of Bacillus cereus with 4 samples.

How the data were processed

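RNA was measured in 4 samples of Bacillus cereus, 1 per condition. BC70 is an isolate from food packaging material and ATCC 14579 is the reference strain. Per the labels' protocols, each sample pooled material before extraction: 4 agar plates for BC70 and for ATCC 14579 with a vancomycin gradient strip (Etest), 12 colonies from 2 plates for BC70 on MH agar, and 2 plates for swarming BC70. The cultures were kept at 37 °C for 13 h. Ribosomal RNA was depleted, the remaining RNA was polyadenylated and reverse transcribed, and barcoded cDNA was sequenced on a nanopore flow cell, per the labels' protocols and descriptions. The labels also state that quality control was kept to a minimum to save material.

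The deposited files are 3 tables of the authors' own comparisons, each setting the BC70 gradient strip sample against 1 other sample. Minimap2, StringTie and edgeR are named in the submitters' processing notes. Their versions, the reference genome, the filters and the scaling are not given in the sources used here. Per the file headers, each deposited table gives for every gene a log2 fold change, a log2 mean CPM value, an F statistic (a score without a fixed range), a p-value and an adjusted p-value. The adjusted p-values equal the Benjamini-Hochberg adjustment of the deposited p-values over each table. Rows are identified by locus tags with the prefix FORC47_RS or by StringTie's own locus numbers. The tables do not pair these identifiers with gene names, and no annotation was used here. The 33 gene lists fixed before the data were examined (biofilm matrix, flagella, cell wall, purines, sporulation, ribosomal RNA and others) matched 0 identifiers, so no gene group could be described and no list result is given. Locus numbers made by StringTie are set anew in each table, so only locus tags were matched between tables.

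The counts behind the deposited log2 values were recovered by computation. Genes with a single count in a group take 2 nearly equal pairs of log2 fold change and log2 mean in each table, as a count in either of 2 columns would give. These pairs fix the library sizes when prior counts of 0.125 and 2 are assumed for the log2 fold change and the log2 mean. Rows with a single count in a whole table gave prior counts that summed to 0.50 in each table, which is the value expected for 2 columns per group. Of the genes with fewer than 10 recovered counts, 100.0%, 99.2% and 99.6% had whole numbers within 0.1 in both groups of the ATCC 14579, MH and swarming tables. These numbers are called implied counts below. Shares of counts use their sums, and folds use the effective library sizes that the single-count genes give. How the authors turned StringTie's estimates into counts is not given in the sources used here, so an implied count is not equated with a sequenced read. Intervals cover counting error only, and floors cover it only in the sample at 0. The files do not say which group a positive fold change favours. The side with positive values had implied counts that matched between tables (within 10% or 1 count) for 90.2% to 91.9% of genes with at least 10 counts, against 7.20% to 11.2% on the negative side. The positive side was therefore taken as the BC70 gradient strip sample, the only sample that all 3 tables share.

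The deposited F statistics and p-values fit an F distribution with 6926, 6884 and 6968 denominator degrees of freedom, which is 2 per gene in each table. A fit of 4 columns to 2 groups has that number. The labels list 1 pooled sample per group and do not describe a second column, so the deposited p-values measure the spread between columns that may be technical. Put into a single negative binomial dispersion, the spread behind the deposited F statistics corresponded to a coefficient of variation of 8.91% in the ATCC 14579 table, 15.0% in the MH table and 11.9% in the swarming table (medians over 91, 113 and 157 genes with at least 100 counts and F above 4). With 1 pooled sample per group no test of biological replication was possible. A gene is called changed where the authors' adjusted p is under 0.05, and such a call compares 2 sequenced pools and not the conditions.

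Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The recovery of counts was tested on simulated tables with 200 genes changed 4-fold. All simulated genes with fewer than 10 counts were recovered exactly in the 3 simulated comparisons, and the median error of larger counts was 0.306%, 0.321% and 0.468% for ATCC 14579, MH and swarming. The simulated tables were written with the same prior counts and 4 columns that the recovery assumes. Exact recovery therefore does not test those assumptions. The changed genes were drawn only from genes with at least 20 counts. A likelihood ratio test on recovered counts, given the simulated dispersion, found 85%, 82% and 89.5% of them in 3093, 3072 and 3152 simulated genes. It made 15, 5 and 9 false calls. These rates do not cover genes with fewer counts. Folds of genes at 0 in a sample were computed against a floor of 3 counts in that sample. Such folds are written with 'at least', take the count in the other sample as exact and are not interval limits. Exact Clopper-Pearson intervals at the 95% level were used for other ratios. Because all comparisons share the BC70 gradient strip sample, overlaps of calls are given beside the product of the list sizes over the number of genes and beside 100 simulated sets of unchanged libraries, first with the spread of the deposited tests and then, as a choice made after seeing the data, with 20% and 40% variation between pools.

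By the rule fixed before the data were examined, each comparison names the identifiers with the 2 highest and the 2 lowest log2 fold changes among called genes at or above the table's median expression. Alternatives fixed at the same time were a threshold of 0.01, an added 2-fold minimum, an expression filter, centring on the median gene and a Bonferroni adjustment. Alternatives added after seeing the data were assumed variation of 20% and 40% between cultures, restriction to genes with matching BC70 gradient strip counts, centring on genes with at least 20 counts, and an indirect contrast over all genes.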

Results

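Transcript levels were compared between the Bacillus cereus isolate BC70, described by the series as pseudo-resistant to vancomycin, and the reference strain ATCC 14579, which showed no resistance in the same susceptibility test. Vancomycin is a glycopeptide antibiotic that blocks cell wall synthesis. Both strains were grown on MH agar carrying a strip with a gradient of the drug, and BC70 was also grown on plain MH agar and as a swarming culture on 0.7% agar. There was 1 pooled sample per condition, so no value below has a replicate error. The implied counts summed to 45662 to 48997 for BC70 on the gradient strip, depending on the table, 62704 for ATCC 14579, 63285 for BC70 on MH agar and 76520 for swarming BC70. The effective library sizes, by which folds were scaled, were 46836 to 49170, 60835, 62334 and 74802 in the same order.

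Between 64.2% and 68.0% of the genes in each table had fewer than 10 counts in both groups together, and only 730, 771 and 801 genes reached 20 counts against ATCC 14579, MH agar and swarming. A single locus, FORC47_RS26370, was the most abundant in every library and was chosen for mention after its values were seen. It held 15.7% to 16.7% of the counts of BC70 on the gradient strip, 18.2% of those of ATCC 14579 and 12.2% of those of BC70 on MH agar. In swarming BC70 its share was 4.69%. The authors' deposited table gave it a log2 fold change of 1.79 between gradient strip and swarming BC70 (adjusted p = 2.51e-34), while its adjusted p was 0.236 against ATCC 14579 and 0.503 against MH agar.

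The first comparison asked how BC70 differed from ATCC 14579 when both grew beside the vancomycin strip. The authors' deposited table listed 114 genes as higher and 72 as lower in BC70 among 3463 tested, at an adjusted p under 0.05. The median log2 fold change in the authors' deposited table was 3.92 for the higher genes and -1.62 for the lower genes. With the 38 higher and 8 lower genes that were at 0 in 1 strain held at the 3-count floor, the medians were 2.60 and -1.54, and 73 higher and 25 lower genes reached 4-fold. The higher genes made up 15.0% of the BC70 counts and 4.22% of the ATCC 14579 counts, and the lower genes made up 7.53% and 17.2%. Of the genes with at least 10 counts in BC70, 24 (3.60%) were at 0 in ATCC 14579, and of those with at least 10 counts in ATCC 14579, 8 (1.07%) were at 0 in BC70.

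The largest difference belonged to FORC47_RS17855, with 132 implied counts in BC70 and 0 in ATCC 14579. Against the 3-count floor it was at least 56.6-fold higher in BC70. Floor folds here and below take the other count as exact, so they are not interval limits. The authors' deposited table gave FORC47_RS17855 a log2 fold change of 9.19 (adjusted p = 7.00e-37). FORC47_RS13680 had 113 counts against 0 and was at least 48.5-fold higher in BC70, with a log2 fold change of 8.97 in the authors' deposited table (adjusted p = 2.07e-32). In BC70 itself these loci were also detected away from the strip, with 35 and 21 counts on MH agar and 72 and 3 counts in the swarming culture. Both were still called higher beside the strip than in each of those libraries, in calls that share the gradient strip library. In the other direction, FORC47_RS25730 had 0 counts in BC70 and 24 in ATCC 14579, at least 6.21-fold lower in BC70, and FORC47_RS04615 had 0 and 19, at least 4.92-fold lower. Their log2 fold changes in the authors' deposited table were -6.43 (adjusted p = 4.35e-05) and -6.10 (adjusted p = 6.46e-04). FORC47_RS04615 was detected in BC70 away from the strip, with 4 counts on MH agar and 21 in the swarming culture. The authors' deposited adjusted p for strip against MH agar was 0.470. Only the swarming count was near that of ATCC 14579, so whether the locus is low in BC70 as a strain is open. FORC47_RS25730 was listed in neither of those comparisons. The deposited test used a spread between columns of 8.91%, and with an assumed variation between cultures of 20% or 40%, set after seeing the data, 116 or 46 of the 186 calls passed. Called genes had at least 7 counts, so differences in genes below that count were not detectable at this depth.

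The second comparison set BC70 on the gradient strip against BC70 on plain MH agar, within the strain. The samples differed in more than the drug. The labels give 4 plates and a McFarland value (a turbidity standard) of 0.5 for the strip sample. For MH agar they give 12 colonies from 2 plates and no such value. Effects of the drug cannot be told apart from these differences. The authors' deposited table called 125 genes higher and 97 lower beside the strip among 3442 tested. Centred on genes with at least 20 counts and held to at least 2-fold, a choice made after seeing the data, the split was 125 higher and 64 lower. The median log2 fold change in the authors' deposited table was 3.23 for the higher and -1.63 for the lower genes. With the 35 higher and 6 lower genes at 0 in 1 sample held at the floor, the medians were 2.35 and -1.52, and 80 and 34 genes reached 4-fold. Genes called higher accounted for 14.8% of the counts beside the strip and 3.24% of those on MH agar, while genes called lower accounted for 8.69% and 20.9%. Genes with at least 10 counts in one sample and 0 in the other numbered 17 with counts only beside the strip and 6 with counts only on MH agar.

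FORC47_RS21015 had 40 counts beside the strip and 0 on MH agar, at least 17.7-fold higher, and FORC47_RS10680 had 39 and 0, at least 17.3-fold higher. The authors' deposited table gave log2 fold changes of 7.50 for FORC47_RS21015 (adjusted p = 1.33e-10) and 7.47 for FORC47_RS10680 (adjusted p = 2.32e-10). Both loci were also called higher in the comparisons with ATCC 14579, where they had 7 counts and 1 count, and with swarming BC70, where they had 2 and 5. FORC47_RS03810 and FORC47_RS03825 had 0 counts beside the strip and 16 and 15 on MH agar, at least 4.01-fold and 3.76-fold lower. Their log2 fold changes in the authors' deposited table were -5.85 (adjusted p = 3.22e-03) and -5.74 (adjusted p = 5.09e-03). In ATCC 14579, FORC47_RS03810 and FORC47_RS03825 had 11 and 4 counts, and neither was listed in the comparison with swarming BC70. The spread used for this table was 15.0%, and 141 or 26 of the 222 calls passed with an assumed variation of 20% or 40%.

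The third comparison set BC70 on the gradient strip against swarming BC70 and gave the most calls. These samples also differed in more than the drug. For the swarming culture the labels give 2 plates, a spotted volume of 5 µl and 0.7% agar, and no McFarland value. Effects of the drug or of swarming cannot be told apart from these differences. The authors' deposited table listed 193 genes as higher and 218 as lower beside the strip among 3484 tested. The majority of lower genes depended on the genes used for centring: with the same centring and 2-fold minimum, 193 were higher and 177 lower, while centring on the median of all genes, fixed before the data were examined, gave 188 and 212. The median log2 fold change in the authors' deposited table was 3.17 for the higher and -2.15 for the lower genes. With the 34 higher and 28 lower genes at 0 in 1 sample held at the floor, the medians were 2.64 and -1.80, and 137 and 92 genes reached 4-fold. Genes higher beside the strip held 44.0% of the counts there and 8.78% of those of the swarming culture, and genes lower beside the strip held 17.3% and 52.5%. FORC47_RS26370 alone contributed 16.7% and 4.69% to the first pair of shares. Genes with at least 10 counts in one sample and 0 in the other numbered 12 with counts only beside the strip and 21 with counts only in the swarming culture.

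FORC47_RS20055 had 1 implied count beside the strip and 461 in the swarming culture, where it was 303-fold higher (95% exact interval 54.1 to 11995). The authors' deposited table gave FORC47_RS20055 a log2 fold change of -8.13 (adjusted p = 1.87e-56). It had 20 counts in ATCC 14579. FORC47_RS20060 had 0 and 33 counts, at least 7.23-fold lower beside the strip, with a log2 fold change of -6.82 in the authors' deposited table (adjusted p = 5.39e-06). FORC47_RS30240 had 42 counts beside the strip and 0 in the swarming culture, at least 21.3-fold higher, and FORC47_RS12650 had 39 and 0, at least 19.8-fold higher. Their log2 fold changes in the authors' deposited table were 7.69 (adjusted p = 7.63e-13) and 7.58 (adjusted p = 7.73e-12). Both were also called higher against ATCC 14579, where they had 0 and 4 counts, and against MH agar, where they had 8 and 14. The spread used was 11.9%, and with an assumed variation of 20% or 40%, 320 or 84 of the 411 calls passed. All genes passing at 20% numbered 342 and split into 190 higher and 152 lower, and those at 40% into 55 and 29. The majority of lower genes was thus not kept in these recounts. As some genes passing at 20% were not among the deposited calls, the recounts may differ from the deposited test in more than the spread.

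**Figure D1:**
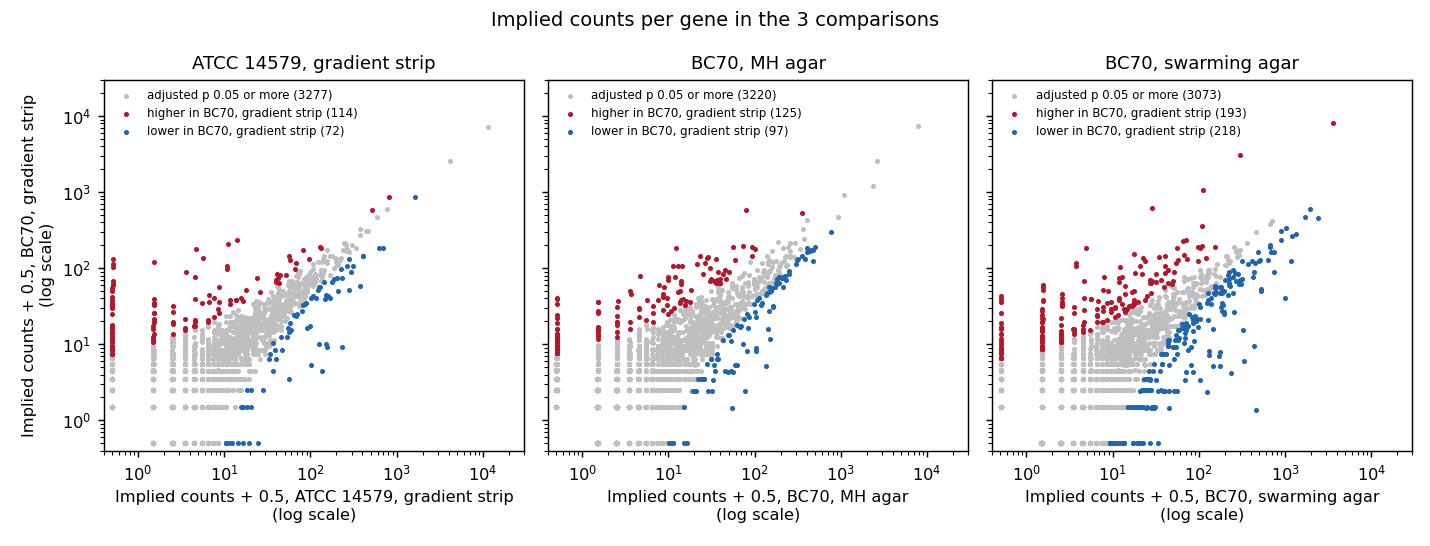
Implied counts per gene plus 0.5 (log scales) in BC70 on the gradient strip (vertical) against ATCC 14579 on the gradient strip, BC70 on MH agar and swarming BC70 (horizontal). Each point is a gene of 1 pooled sample per group, and colours mark an adjusted p under 0.05 in the authors' deposited tables; the swarming panel has the most coloured genes (193 higher and 218 lower).

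Many genes were called in the same direction in more than 1 comparison. Of the 2960 locus tags present in all tables, 65 were higher in BC70 on the gradient strip than in each of the other 3 libraries, and 15 were lower than in each. The 65 genes held 10.01% of the locus tag counts of BC70 beside the strip, and 1.81% in ATCC 14579, 1.78% in BC70 on MH agar and 1.22% in swarming BC70. Their median log2 fold changes were 3.89, 3.40 and 3.94 against these libraries in that order, or 2.89, 2.72 and 3.43 with genes at 0 held at the floor. The 15 genes held 0.586% of the counts beside the strip, and 3.06%, 2.33% and 4.03% in the other libraries. The gradient strip counts matched between tables for 62 of the 65 genes and for 10 of the 15. Within BC70, 100 genes were higher and 55 were lower beside the strip than in both the MH agar and the swarming library.

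The number of shared calls was above the product expected of independent lists, which leaves out the shared library. The product was taken over all shared locus tags, many of which had too few counts to be called. It is therefore too low for independent lists among the genes that could be called. Against ATCC 14579 and MH agar, 74 genes were higher in both and 22 lower in both, where independent lists give 4.24 and 1.99. Against ATCC 14579 and swarming, 79 and 27 were shared, with 6.43 and 4.18 for independent lists. Against MH agar and swarming, 101 and 55 were shared, with 7.51 and 5.78. All comparisons use the same BC70 gradient strip library, so chance values of that library recur in each. Over 669 genes with a mean of at least 10 counts and matching gradient strip counts, 42, 42 and 58 genes were higher in both lists of these pairs and 16, 19 and 46 lower. In 100 simulated sets of unchanged libraries with the spread of the deposited tests 0 genes were shared, but that spread may be technical and leaves out variation between cultures. With an assumed variation of 40% between pools, set after seeing the data, the simulated sets shared at most 21, 16 and 19 higher and 17, 17 and 17 lower genes, and with 20% at most 1 gene in either direction. The covariance of the log2 fold changes over these genes was 1.17, 1.49 and 1.76, against simulated means of 0.172, 0.174 and 0.175 with the spread of the deposited tests and 0.555, 0.562 and 0.556 with 40% variation. The correlation was 0.52, 0.53 and 0.74, against 0.56, 0.58 and 0.58 in the sets with the deposited spread, so in both pairs with ATCC 14579 it lay below the value that sharing the library gives without any effect. The gradient strip pool cannot be split, and how much of the overlap comes from the shared library is open.

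The gradient strip library itself gave unequal implied counts in different tables for a minority of genes. Of the genes with at least 10 counts, 8.06% to 9.83% differed by more than 10% and 1 count between pairs of tables, and 26, 28 and 20 genes differed by more than 2-fold. Of the calls in the deposited tables, 157 of 186, 186 of 222 and 332 of 411 fell on locus tags with matching gradient strip counts in all tables.

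**Figure D2:**
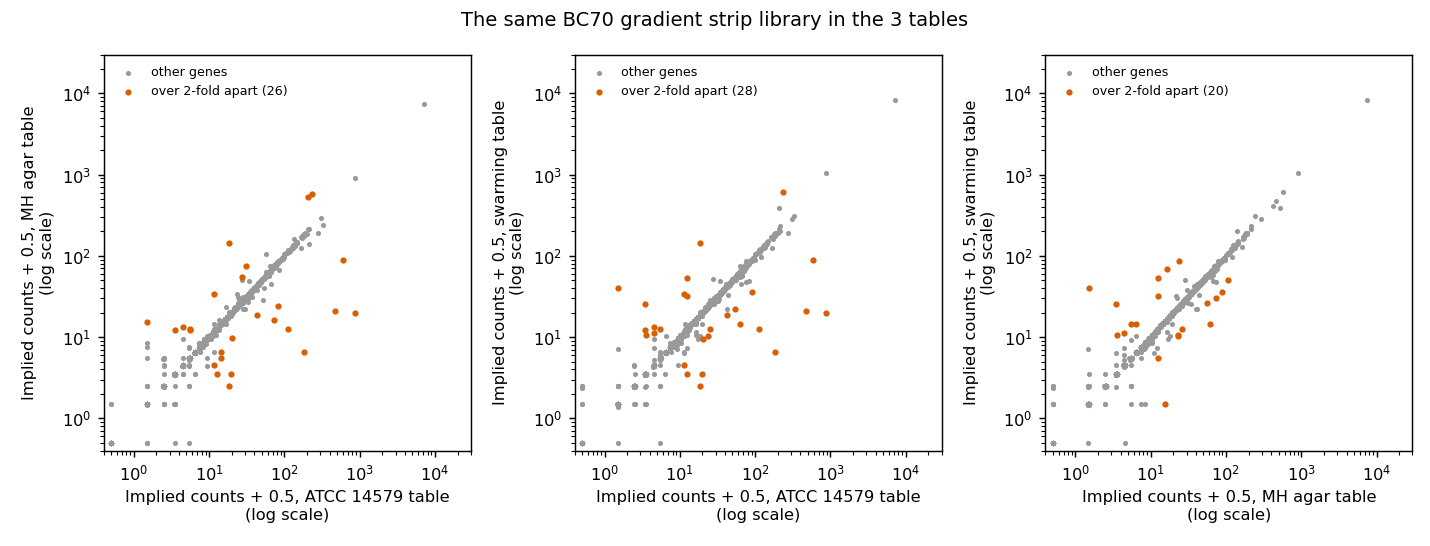
Implied counts per gene plus 0.5 (log scales) of the single BC70 gradient strip library, each panel setting 2 of the 3 deposited tables against each other. Points are locus tags present in both tables, and orange marks the 26, 28 and 20 genes with at least 10 counts that differ by more than 2-fold; the rest lie near the diagonal.

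Swarming BC70 and BC70 on MH agar were set side by side through their common partner. Over 734 genes with matching gradient strip counts and a mean of at least 10 counts in the 2 libraries, 107 were at least 2-fold higher and 90 at least 2-fold lower in the swarming culture, while 537 lay within 2-fold. The 95% exact counting interval lay wholly beyond 2-fold for 35 of the higher and 33 of the lower genes. The log2 differences had an SD across genes of 1.15, close to the 1.20 between gradient strip and MH agar and below the 1.57 between gradient strip and swarming over the same genes. The genes were kept by their MH agar and swarming counts only. Low counts beside the strip can therefore widen the SDs with the gradient strip, and the SDs are not on equal terms. This contrast has no test, and each table was scaled separately.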

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

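The choice of threshold and the recounts with an assumed spread moved the counts of called genes most. Against ATCC 14579 the 186 calls became 122 at an adjusted p under 0.01 and 84 with a Bonferroni adjustment, which left 78 of 222 calls against MH agar and 180 of 411 against swarming. With variation between cultures assumed, as a choice made after seeing the data, the counts were 116 (20%) and 46 (40%) against ATCC 14579, 141 and 26 against MH agar, and 342 and 84 against swarming. At 20% against swarming, 320 of the 342 were among the deposited calls, so that count also holds genes that the deposited test did not call. The recounts may therefore differ from the deposited test in more than the spread. The share of higher genes among the calls then ran from 61.3% to 82.6%, from 56.3% to 88.5% and from 47.0% to 65.5% at 40%. Shared calls at an adjusted p under 0.01 fell to 13 lower genes for ATCC 14579 with MH agar, to 52 higher and 17 lower genes for ATCC 14579 with swarming, and to 34 lower genes for MH agar with swarming. The other 34 alternative totals of the calls, overlaps and the indirect contrast stayed within 1.5 times the deposited setting. Restricting the tables to genes with matching gradient strip counts, also chosen after seeing the data, gave 157, 186 and 332 calls. The expression filter removed no call in any table. The median log2 fold change was 0.28, 0.20 and 0.14 over all genes and -0.09, -0.23 and -0.29 over genes with at least 20 counts. Calls of at least 2-fold split into 107 higher and 60 lower genes against ATCC 14579, 124 and 86 against MH agar, and 189 and 205 against swarming. After centring on genes with at least 20 counts, chosen after seeing the data, these splits were 109 and 56, 125 and 64, and 193 and 177, so the majority turned against swarming. Centring on all genes, as planned, gave 101 and 71, 120 and 96, and 188 and 212. Against swarming the split was also 168 and 164 on genes with matching gradient strip counts and 90 and 90 with a Bonferroni adjustment. No alternative that needs gene names was run, which covers the ribosomal protein scaling and all gene list medians. No paired analysis was possible because each group has 1 pooled sample and the tables carry no replicate numbers; for the same reason no replicate could be left out. Depth limits the low genes: 742, 712 and 687 genes had a single count in a whole table.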

Other observations

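The tests in this part of separate quantification, of another gradient strip library and of tag neighbourhood were chosen after their results had been seen in part, and 1 comparison group marked below was added later. The others were set down before their results were seen. A minority of the called genes lay beside others called in the same direction in the locus tag order, more than in shuffled orders. The shuffled orders were not matched on counts. Most calls fell on genes with at least 20 counts (143 of 186, 175 of 222 and 315 of 411 against ATCC 14579, MH agar and swarming). Neighbours with high counts could therefore add to the runs without a shared change, and how much of the excess this makes was not tested. Among the 395 locus tags called against swarming, 110 sat in runs of at least 3 consecutive tags, 40 of them higher and 70 lower beside the strip. In 1000 shuffled orders the mean was 1.81 genes and the highest 12. The corresponding numbers were 28 of 182 tags against ATCC 14579 (highest shuffled 6) and 43 of 218 against MH agar (highest shuffled 6). The longest run lower beside the strip than in the swarming culture held 7 tags with 440 against 2178 counts. The longest run higher beside the strip than on MH agar held 6 tags with 455 against 64 counts and log2 fold changes of 2.58 to 4.54.

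A candidate explanation for these runs is that tag numbers follow the order of genes and that neighbours are transcribed together. Over genes with at least 5 counts, the rank correlation of the deposited fold changes between adjacent tags was 0.35, 0.49 and 0.49 against ATCC 14579, MH agar and swarming. It was 0.01, 0.08 and 0.06 at a distance of 20 tags, and the highest of 1000 shuffled orders at a distance of 1 tag was 0.10. Genes are not independent replicates, so these values describe the libraries. Counts shared only between direct neighbours would stop there. At a distance of 3 tags the correlation was still 0.14, 0.23 and 0.25, above the shuffled 95% range in every table. This argues against sharing between direct neighbours as the whole source. Reads or gene models that span several genes were not examined, so sharing of counts over longer stretches cannot be told apart from joint transcription. Joint transcription of neighbours stays open as the biological explanation.

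The same BC70 gradient strip library had different implied counts in different tables for some genes. By more than 2-fold, 26, 28 and 20 genes with at least 10 counts differed between the 3 pairs of tables. If another library had entered each table, the squared difference over the sum would be near that of independent counts, yet its median was at most 0.00153, which argues against that explanation. Where the gradient strip count differed, the partner libraries also differed by more than 2-fold in the same direction in 79.7% of 74 cases. Among 1748 cases with matching gradient strip counts, which have no direction of their own, the partner libraries differed by more than 2-fold upward in 15.9% and downward in 17.8%. This is consistent with gene models or read assignment that were set separately for each table, so that a fold change of such a gene may depend on the table. Assembled loci without a locus tag held 8.63% to 13.8% of the gradient strip counts, depending on the table. No biological explanation applies to a single library counted again.

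Genes with counts in BC70 and 0 in ATCC 14579 can be read in different ways. Among genes with at least 20 gradient strip counts, 3.91% were at 0 in ATCC 14579, against 1.28% at 0 in BC70 on MH agar and 1.01% in swarming BC70. Of the 15 genes at 0 in ATCC 14579, 93.3% had counts in both other BC70 libraries, as a sequence that is absent from or diverged in ATCC 14579 would give, although 94.0% of the 369 genes detected in ATCC 14579 had them too. Among the 54 detected genes that were called higher in BC70, a group added after the result was seen, 81.5% had them. Of the same 15 genes, 80% were also called higher beside the strip than in both other BC70 libraries, but so were 66.7% of the 54 genes with at least 20 gradient strip counts that were detected in ATCC 14579 and called higher in BC70, a comparison added after the result was seen. All these calls share the gradient strip library in which the genes were chosen for being high. The tests therefore decide neither for divergence nor for genes raised beside the strip in BC70 alone, and the explanations cannot be told apart here.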
